A study of Homo sapiens with 99 samples.

How the data were processed

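Bulk RNA sequencing measured gene expression in primary CD4+ T cells, the helper T cells of the blood, from children in 4 groups. The 99 libraries comprised 39 from obese children with asthma, 20 from obese children without asthma, 20 from healthy weight children with asthma and 20 from healthy weight children without asthma. The label of the healthy weight asthma libraries gives only the weight, and their asthma status comes from the series' design text. A single-cell part that the design text also mentions was not analysed here. The labels do not say that each library came from a different child, so p-values measure the spread between libraries.

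The deposited table held size-factor-normalized gene counts, a signal that the authors made from their reads. RNA was extracted with a Zymo kit, and the labels' protocols name a Kapa stranded mRNA kit and an mRNA HyperPrep kit for the libraries without saying which library was made with which. Per the submitters' processing notes, FastQC, Trim Galore, STAR and DESeq were used, with the genome build GRCh38 (hg38). Their versions, the counting step, its strand setting and the gene annotation are not given in the sources used here. Reads from near-identical copies and overlapping genes may therefore have been split or dropped. Some of the genes named from a comparison as a whole are marked as uncertain for this, while members named from gene lists carry no such mark. A missing mark does not mean that a gene is free of the problem. The table listed 45080 genes by Ensembl identifier. Of these, 44855 matched GENCODE release 29, which gave positions on GRCh38, and 44488 had a symbol in the reference name table.

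In every library 100.0% of the values were whole multiples of that library's smallest value above 0, within a relative tolerance of 1e-06, so whole reads were recovered. The reads counted per library ranged from 10.7 to 141.7 M with a median of 36.3 M. No library pair looked like a single library deposited more than once: over 4851 pairs the lowest chi-square per degree of freedom between read counts was 16.0.

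The groups and comparisons, the tests, the gene lists, the rule for named genes and 14 alternatives for the gene-level fits were fixed before the data were examined. Normalized counts were tested as log2(value + 1) with limma (lmFit with a mean per group, eBayes with trend and robust moderation) over all 99 libraries in a single fit. Genes needed a mean normalized count of at least 10, which left 17415, and a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Because the values were normalized rather than raw, edgeR's quasi-likelihood test and DESeq2 on the recovered reads served as alternatives. The comparisons set obese asthma against each of the 3 other groups, then asthma within healthy weight children, obesity within children without asthma, and the interaction of obesity and asthma. The 36 gene lists, of T helper subsets, signalling and metabolic pathways, markers of other cell types and RNA quality, were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives.

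For each comparison of obese asthma the rule named the 10 highest and 10 lowest log2 folds among genes past the threshold with a mean normalized count of at least 50. Sex-linked transcripts, HLA genes, antigen receptor segments, pseudogenes and genes without an approved-style symbol were left out. Where no gene passed in a direction, the 5 smallest p-values in it were given as values; other comparisons took 5 per direction. For each list the rule named up to 4 members with the smallest p. Which lists are described at length, and which of those members are named, was chosen after their values were seen.

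Technical classes of libraries were defined after the data were examined, from the RPL21 level and the number of reads. RPL21 separated the libraries with a gap from 11.51 to 13.51 on the log2 scale, and the reads with a gap from 54.5 to 81.4 M. Class 1 had high RPL21 (60 libraries), class 2 low RPL21 and fewer than 70.0 M reads (23), and class 3 low RPL21 and more than 70.0 M reads (16). The labels give no batch, and whether the classes match the kits is not given in the sources used here. Fits with class as a covariate, fits within a class, and a fit on reads thinned to 10 M per library were therefore added after seeing the data, as 8 further gene-level alternatives.

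Limma with and without class and camera at the preset correlation were tested on simulated data. So were edgeR and DESeq2 without class for obese asthma against obese no asthma. The simulation had 17415 genes drawn from the real means and library sizes and 200 genes changed. The other alternatives and the splits were not tested in this way. With class differences simulated and no group effect on the other genes, limma without a class term made 1027 false calls for obese asthma against obese no asthma and 1285 against healthy weight no asthma. For healthy weight asthma against healthy weight no asthma it made 38 among 148 calls. With class as a covariate it made 6, 6 and 6. For obese asthma against healthy weight asthma limma made 11 false calls without class and 10 with it. Genes were drawn independently in the simulation, so these counts do not show the false calls that arise when genes move together. At a fold of 2, the fit with class recovered 83.3% of the changed genes for obese asthma against obese no asthma, 84.8% against healthy weight asthma and 84.8% against healthy weight no asthma. At a fold of 1.5 it recovered 58.2%, 58.2% and 53.7%. For the interaction, recovery was 60.6% at a fold of 2. Without class differences simulated, the planted gene list was found and 0 of the unchanged lists were called by camera. Genes were drawn independently there, so this does not check the preset correlation or the effect of class on list calls.

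The share of other groupings giving as many genes was counted over 100 splits drawn with a fixed seed, the real one included. For the genes shared by comparisons, the group labels were reassigned at random 100 times over all libraries and, after the data had been seen, 100 times within the technical classes. Sex-linked genes entered a covariate in an alternative and are not reported. Some other genes and a gene list that were tested are not reported here. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.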

Results

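The study set CD4+ T cells of obese children with asthma beside those of obese children without asthma and of healthy weight children with or without asthma, by bulk RNA sequencing of 99 libraries. The obese asthma group held 39 libraries and each of the 3 other groups held 20. Depth differed between the groups, with a median of 29.97 M reads per library in obese asthma, 41.7 M in obese no asthma, 33.6 M in healthy weight asthma and 49.8 M in healthy weight no asthma.

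The libraries fell into 3 technical classes that the labels do not name and that were spread unevenly over the groups. RPL21, which encodes a protein of the large ribosomal subunit and has many processed pseudogenes, averaged 14.54 ± 0.34 on the log2 scale (SD, n = 60) in class 1, 10.80 ± 0.23 (SD, n = 23) in class 2 and 11.17 ± 0.23 (SD, n = 16) in class 3. Class 3 held the deepest libraries, with a median of 100.7 M reads, against 28.03 M in class 1 and 44.6 M in class 2. Obese asthma had 33, 5 and 1 libraries in classes 1, 2 and 3, obese no asthma 7, 7 and 6, healthy weight asthma 13, 6 and 1, and healthy weight no asthma 7, 5 and 8. Markers of monocytes, a blood cell type outside the CD4+ T cells, also differed by class, with a mean log2 level of 7.40 ± 1.26 (SD, n = 60) in class 1, 8.65 ± 1.06 (SD, n = 23) in class 2 and 9.54 ± 1.53 (SD, n = 16) in class 3. Values with class as a covariate therefore stand beside the pooled ones for the genes named from each comparison as a whole, and within-class values for part of them. For the members named from gene lists they stand beside only some of the pooled values. For the lists themselves either the test with class or the number of lists that kept their call is given.

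**Figure D1:**
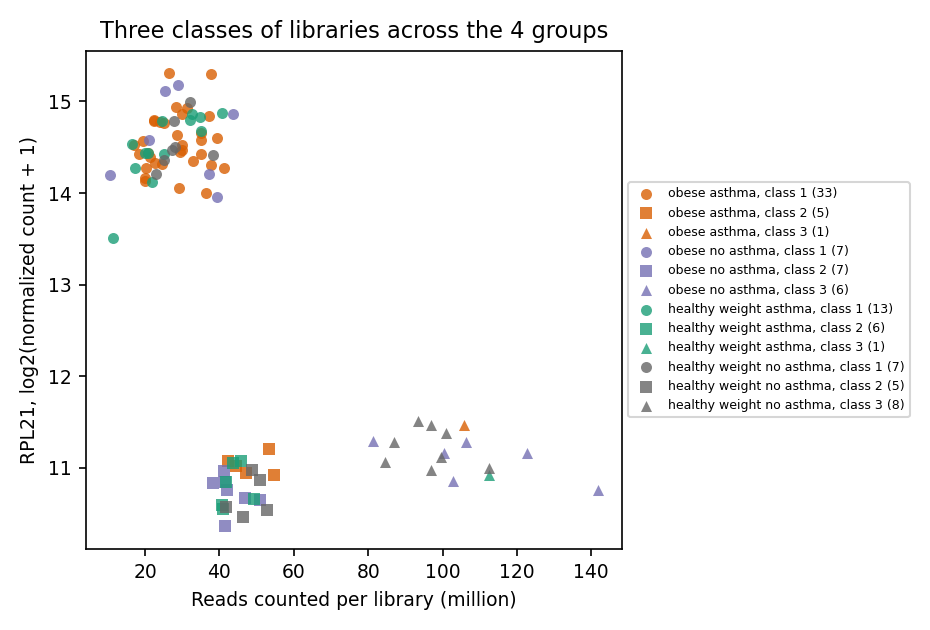
Reads counted per library in M (mega, horizontal) against the RPL21 level as log2(normalized count + 1) (vertical), a point per library, coloured by group and shaped by technical class, with the number of libraries in the key. No library lies between 11.51 and 13.51 in RPL21, and 33 of the 39 obese asthma libraries are in class 1 against 7 of 20 in each group without asthma.

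The comparison of obese children with and without asthma asked what goes with asthma when weight is alike. Monocyte transcripts and several chemokine genes were lower in obese asthma (n = 39) than in obese no asthma (n = 20). CCL3, a chemokine (ENSG00000277632, chromosome 17, 36088256 to 36090169 of GRCh38, minus strand) that is uncertain because it shares reads with near-identical copies, fell by 2.79 ± 0.54 on the log2 scale (SE). CD14, the monocyte receptor for bacterial lipopolysaccharide, fell by 2.34 ± 0.58. Its log2 level was 14.10 and 12.33 in single obese no asthma libraries of class 3, with the rest of that group at 10.36 or lower. CXCL8, the neutrophil-attracting chemokine, fell by 2.31 ± 0.57, and S100A8 and S100A12, calcium-binding proteins of myeloid cells, fell by 2.19 ± 0.61 and 2.11 ± 0.56. Among the genes that rose, NR4A3, an activation-induced nuclear receptor, rose by 1.75 ± 0.50, and RGS16, a regulator of G protein signalling, by 1.34 ± 0.33. With technical class as a covariate these log2 differences were −1.31 ± 0.43 for CCL3, −0.93 ± 0.53 for CD14, −1.08 ± 0.50 for CXCL8, −0.89 ± 0.58 for S100A8, −1.03 ± 0.54 for S100A12, 0.60 ± 0.45 for NR4A3 and 0.50 ± 0.28 for RGS16, and none passed the test. In classes 1 and 2 CCL3 was at −1.69 and −0.52, CD14 at −0.67 and −1.52, NR4A3 at 0.34 and 2.46, and RGS16 at 0.41 and 1.27.

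In all, limma called 2571 genes at an adjusted p under 0.05, 1427 lower and 1144 higher in obese asthma. The split turned to 851 lower and 1659 higher after quantile normalization. Given class as a covariate, limma called 0 genes, with 582 at an unadjusted p under 0.05, and edgeR with class called 3. Within class 1 alone limma called 0 (315 at an unadjusted p under 0.05), and within class 2 alone 0 (3484). The plot of gene counts by fit shows this loss beside the other comparisons.

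**Figure D2:**
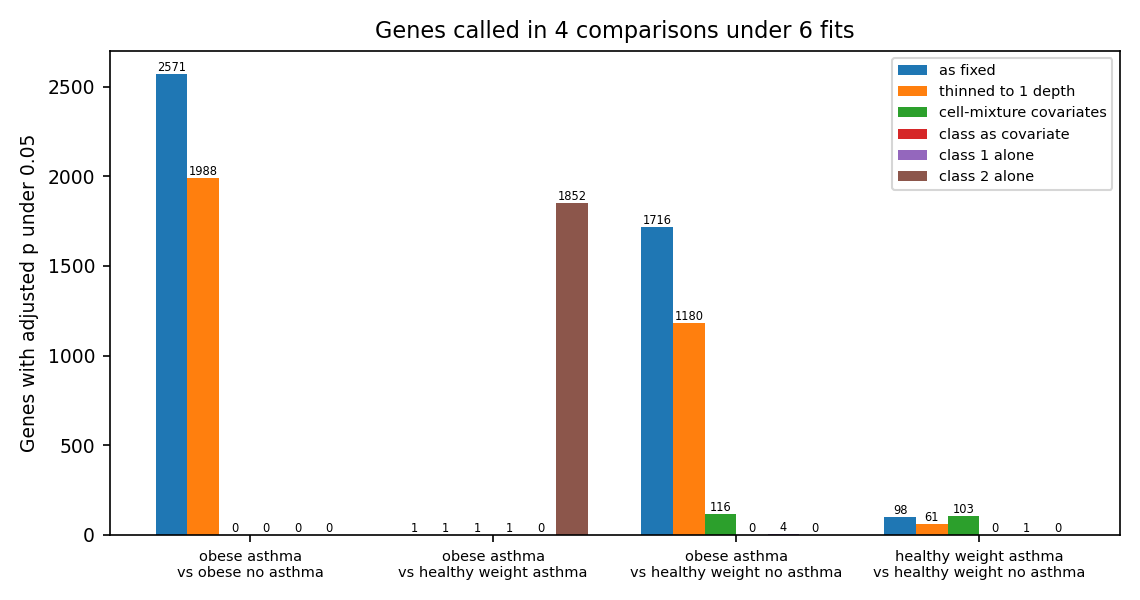
Number of genes with a limma adjusted p under 0.05 (vertical) in 4 comparisons (horizontal), with a bar for each of 6 fits. The counts of 2571 and 1716 without a covariate for obese asthma against the groups without asthma become 0 with class as a covariate. On reads thinned to an equal depth the counts are 1988 and 1180.

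The other genes named by the rule as higher were RPS26 (log2 difference 1.93 ± 0.50, SE), RPL21 (1.84 ± 0.44), ZNF331 (1.54 ± 0.38), DBH (1.40 ± 0.38), ULBP2 (1.35 ± 0.41), the cholesterol synthesis enzyme gene SC5D (1.31 ± 0.35), GPR132 (1.26 ± 0.31) and EPGN (1.24 ± 0.35). RPS26 and RPL21 share reads with near-identical pseudogenes and are uncertain; RPL21 also defines the classes, and their log2 differences with class as a covariate were 0.17 ± 0.28 and 0.10 ± 0.09. Within class 1 alone they turned to −0.17 and −0.03. The 6 others were between 0.25 (SC5D) and 0.77 (DBH) with class as a covariate, between 0.07 (ULBP2) and 0.50 (GPR132) within class 1 and between 1.03 (GPR132) and 1.83 (DBH) within class 2. Lower were GSTM1 (−2.99 ± 1.06), a detoxifying enzyme gene often deleted in human genomes, CCL3L3 (−2.25 ± 0.61), a near-identical copy of CCL3 and uncertain like it, AQP9 (−2.22 ± 0.59), G0S2 (−2.19 ± 0.54) and the haemoglobin gene HBB (−2.13 ± 0.63). GSTM1 was at −3.36 ± 1.16 with class as a covariate, no longer past the test at a limma adjusted p of 0.984, and CCL3L3, AQP9, G0S2 and HBB were at −0.84, −1.29, −0.77 and −1.15. HBB turned to 0.25 ± 0.32 with cell-mixture covariates, and G0S2 to 0.01 within class 2. These covariates were the levels of monocyte, platelet, B cell and red blood cell markers, and HBB is itself among the last.

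**Figure D3:**
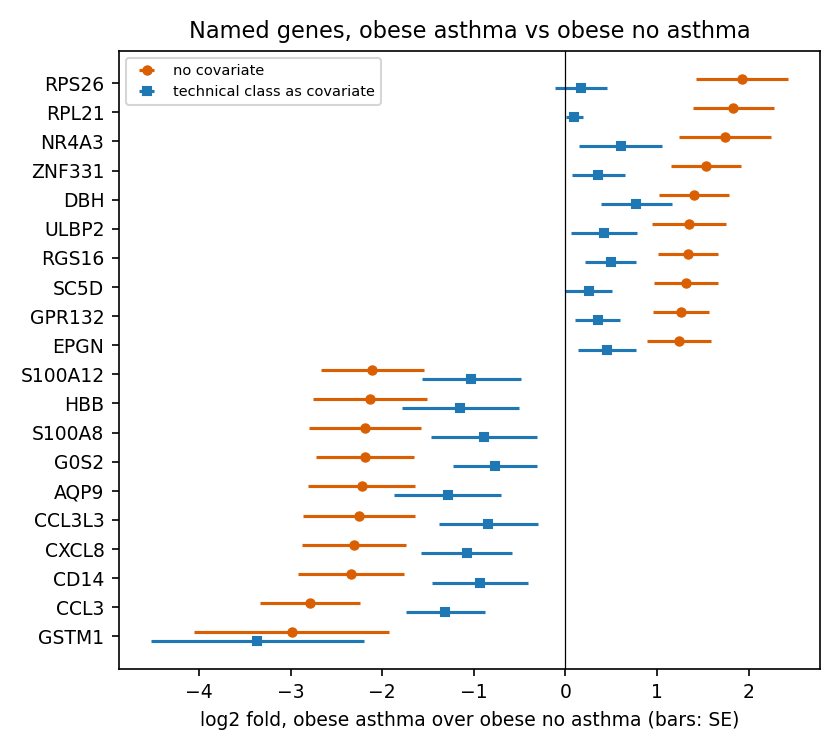
Log2 fold of obese asthma (n = 39) over obese no asthma (n = 20) for the 20 genes named by the rule, with bars of 1 SE, without a covariate (circles) and with technical class as a covariate (squares). RPS26 and RPL21 move from 1.93 and 1.84 to 0.17 and 0.10, and CCL3 moves from −2.79 to −1.31.

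Markers of other blood cells were lower together in obese asthma. Of 19 monocyte markers 13 fell, among them CYBB (−1.40 ± 0.36) and S100A9 (−2.09 ± 0.55), and 19 fell when adjusted over the list alone (camera adjusted p = 5.59e-08; adjusted p = 0.444 with an estimated correlation). Their mean log2 level was 7.57 ± 1.12 (SD, n = 39) in obese asthma and 8.92 ± 1.80 (SD, n = 20) in obese no asthma. The median log2 difference of the monocyte markers was −1.11 by limma, −1.96 in edgeR and −2.02 in DESeq2. Of 13 B cell markers 8 fell, including CD79A (−1.22 ± 0.29), and 11 adjusted over the list alone (camera adjusted p = 5.33e-05; adjusted p = 0.444 with an estimated correlation). All 6 plasma cell markers fell, such as MZB1 (−1.44 ± 0.41), a chaperone of antibody-secreting cells (camera adjusted p = 9.77e-04; adjusted p = 0.444 with an estimated correlation). With class as a covariate the camera adjusted p of these 3 lists was 2.43e-05, 0.0026 and 0.0073, with median log2 differences of −0.43, −0.41 and −0.54 and 0 members past the test.

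Cytotoxic, interferon and mitochondrial respiration genes were lower as groups as well. Of 20 effector memory and cytotoxic genes 5 fell, with PRF1, the pore-forming perforin, at −0.80 ± 0.22 and NKG7 at −0.95 ± 0.31, and 15 fell adjusted over the list alone (camera adjusted p = 5.33e-05; adjusted p = 0.444 with an estimated correlation). NKG7 turned to 0.24 within class 2. Of 32 type I interferon genes 6 fell, including IFI6 (−0.73 ± 0.19) and IFIT2 (−0.70 ± 0.20), and 7 adjusted over the list alone (camera adjusted p = 0.0052; adjusted p = 0.562 with an estimated correlation). Of 75 nuclear-encoded oxidative phosphorylation genes 25 fell and 1 rose, with ATP5PF at −0.42 ± 0.10 and COX5B at −0.47 ± 0.12, and 33 fell and 2 rose adjusted over the list alone (camera adjusted p = 2.61e-05; adjusted p = 0.444 with an estimated correlation). Adjusted for class, the cytotoxic, interferon and oxidative phosphorylation lists had a camera adjusted p of 4.92e-04, 8.07e-06 and 0.0153. Markers of cells that share the cytotoxic genes were lower in the same comparison. Of 10 NK cell markers 3 fell, and 6 adjusted over the list alone (median −0.71; camera adjusted p = 0.0156; adjusted p = 0.444 with an estimated correlation; camera adjusted p = 0.172 with class). Of 6 gamma delta and MAIT cell markers 3 fell, and 4 adjusted over the list alone (median −0.60; camera adjusted p = 0.0259; adjusted p = 0.444 with an estimated correlation; camera adjusted p = 0.0321 with class).

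Of 25 NF-kB and TNF signalling genes 4 rose and 0 fell, over all genes and adjusted over the list alone. They were NFKB1 (0.48 ± 0.10), a subunit of the transcription factor, RELA (0.26 ± 0.08), its partner subunit, TNFAIP3 (0.65 ± 0.17), its feedback inhibitor, and RIPK1 (0.27 ± 0.09), a kinase of the TNF receptor (camera adjusted p = 0.0202; adjusted p = 0.444 with an estimated correlation; camera adjusted p = 8.80e-04 with class as a covariate). Of 22 glucocorticoid response genes 4 rose and 1 fell, with the receptor gene NR3C1 at 0.40 ± 0.10 and CXCR4 at 0.56 ± 0.15, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.0259; adjusted p = 0.444 with an estimated correlation). Of 35 insulin, PI3K and mTOR genes 9 rose and 2 fell, with FOXO1 at 0.37 ± 0.09 and SESN3 at 0.53 ± 0.16, and 10 and 2 adjusted over the list alone (camera adjusted p = 0.0202; adjusted p = 0.444 with an estimated correlation). Of 12 measured Th2 genes CCR4 (0.77 ± 0.19), GATA3 (0.40 ± 0.10), the lineage's master regulator, and IL4R (0.42 ± 0.12) rose, and the list missed the threshold (camera adjusted p = 0.0576). The T cell receptor list was called higher (camera adjusted p = 0.0135; adjusted p = 0.444 with an estimated correlation), with 6 members higher and 1 lower (8 and 1 adjusted over the list alone), but its median log2 difference of 0.07 turned to −0.02 after quantile normalization. For cytosolic ribosomal proteins camera gave higher and the mean was 0.09, while the median was −0.01 (camera adjusted p = 0.0444; adjusted p = 0.702 with an estimated correlation). Adjusted for class, the camera adjusted p was 0.0147 for glucocorticoid response, 0.0875 for insulin, PI3K and mTOR, 0.393 for the T cell receptor list and 0.447 for ribosomal proteins. For Th2, not called without class, it was 8.80e-04, and 0.498 with an estimated correlation as well. Camera called 18 of 36 lists here, 6 up and 12 down, of which 11 kept direction and call with class as a covariate and 0 held with an estimated correlation. No list was called with class and an estimated correlation together.

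Among children with asthma, obese against healthy weight, a single gene passed. BCL3, a nuclear cofactor of NF-kB (ENSG00000069399, chromosome 19, 44747705 to 44760044 of GRCh38, plus strand), was 1.84-fold higher in obese asthma, a log2 difference of 0.88 ± 0.16 (SE; limma adjusted p = 0.0038). Its log2 level was 11.37 ± 0.64 (SD, n = 39) in obese asthma, 10.49 ± 0.62 (SD, n = 20) in healthy weight asthma, 11.16 ± 0.46 (SD, n = 20) in obese no asthma and 11.005 ± 0.52 (SD, n = 20) in healthy weight no asthma. In 37 of the 39 obese asthma libraries BCL3 lay above the healthy weight asthma mean. The means of the groups without asthma lay above that mean as well, so the count is not particular to obese asthma. With class as a covariate the log2 difference was 0.83 ± 0.16 (limma adjusted p = 0.0121). Within class 1 alone it was 0.65 ± 0.19, which did not pass over all genes (limma adjusted p = 0.9998), and within class 2 alone it was 1.48 (limma adjusted p = 0.0115).

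**Figure D4:**
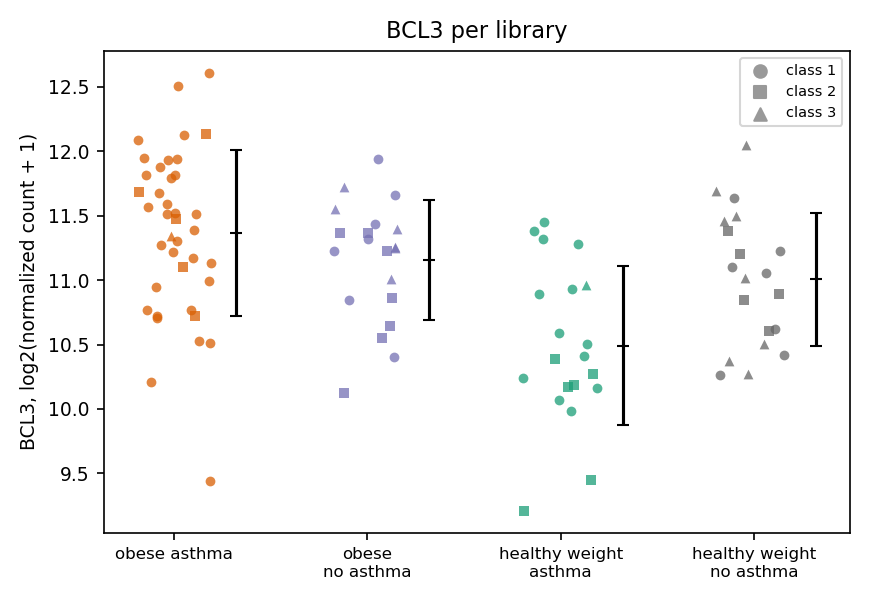
BCL3 level as log2(normalized count + 1) (vertical) in each library by group (horizontal), with point shape for technical class and a black bar for the group mean with 1 SD. Healthy weight asthma is lowest at 10.49 ± 0.62 and obese asthma highest at 11.37 ± 0.64, with the groups without asthma between them.

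By limma no gene passed as lower. The smallest p-values in that direction belonged to BTN2A2 (−0.35 ± 0.09), RHOBTB3 (−0.67 ± 0.18), XPNPEP3 (−0.19 ± 0.05), ZNF555 (−0.32 ± 0.09) and SYNPO2 (−0.52 ± 0.14), with limma adjusted p from 0.260 to 0.329. Adjusted for class, these 5 lay between −0.72 (RHOBTB3) and −0.20 (XPNPEP3). Limma had 1577 genes at an unadjusted p under 0.05, and by adjusted p edgeR called 25 genes, 21 of them lower, and DESeq2 190, of which 167 were lower. The count was 0 within class 1 and 1852 within class 2 alone, the latter falling to 149 or 176 without either of 2 obese asthma libraries.

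Several gene lists were called in this comparison. Of 25 NF-kB and TNF genes 22 had positive log2 differences, BCL3 passed over all genes, and 5 rose adjusted over the list alone, including TNIP2 (0.24 ± 0.07), NFKB1 (0.32 ± 0.10) and RELA (0.25 ± 0.08) (camera adjusted p = 8.22e-07; adjusted p = 0.273 with an estimated correlation). Of 79 cytosolic ribosomal protein genes 76 were positive, with a median log2 difference of 0.11, or 0.04 after quantile normalization, and 0 past the test (camera adjusted p = 2.74e-11; adjusted p = 0.419 with an estimated correlation). Of 19 leptin and adipokine genes 5 rose and 1 fell adjusted over the list alone; STAT3, which relays leptin signals, was at 0.39 ± 0.11, the leptin pathway inhibitor SOCS1 at 0.58 ± 0.16 and NAMPT at 0.60 ± 0.23, while the median of 0.06 was 0.03 in edgeR and 0.01 in DESeq2 (camera adjusted p = 0.0119; adjusted p = 0.395 with an estimated correlation). Type I interferon genes were lower, with 0 of 32 past the test, IFIT2 at −0.53 ± 0.20 and OAS1 at −0.59 ± 0.27 (camera adjusted p = 1.22e-06; adjusted p = 0.419 with an estimated correlation). Effector memory and cytotoxic genes were lower, with 0 of 20 past the test, FCRL6 at −1.08 ± 0.38 and CX3CR1 at −0.66 ± 0.32 (camera adjusted p = 6.24e-05; adjusted p = 0.419 with an estimated correlation). Among markers of other cells the gamma delta and MAIT list (median −0.32; camera adjusted p = 0.0279; adjusted p = 0.395 with an estimated correlation) and the eosinophil and basophil list (median −0.37; camera adjusted p = 0.0251; adjusted p = 0.558 with an estimated correlation) were lower, with 0 members past the test. The CD8 T cell list (median −0.46; camera adjusted p = 0.0605), the NK cell list (median −0.32; camera adjusted p = 0.152) and the monocyte list (median −0.10; camera adjusted p = 0.298) were not called. The monocyte median was −0.49 in edgeR and −0.53 in DESeq2, so a lower monocyte share is not excluded here. Camera called 12 of 36 lists, 8 up and 4 down; 11 of them kept direction and call with class as a covariate, and 0 held with an estimated correlation.

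Obese asthma against healthy weight no asthma set both conditions against neither. The regulatory T cell genes IL2RA (0.62 ± 0.15, SE), the interleukin 2 receptor alpha chain, FOXP3 (0.38 ± 0.11), the lineage's transcription factor, IKZF4 (0.37 ± 0.08) and F5 (0.44 ± 0.14) rose in obese asthma (n = 39 against 20), 4 of 15 measured and 4 adjusted over the list alone (camera adjusted p = 0.0257; adjusted p = 0.570 with an estimated correlation). F5 encodes coagulation factor V. The Th2 genes GATA3 (0.47 ± 0.10) and IL4R (0.45 ± 0.12) rose, 2 of 12 measured and 3 adjusted over the list alone (camera adjusted p = 0.0257; adjusted p = 0.570 with an estimated correlation). Adjusted for class, these lists had a camera adjusted p of 9.85e-04 and 0.003, and the log2 differences of IL2RA, FOXP3, GATA3 and IL4R were 0.50 ± 0.17, 0.31 ± 0.12, 0.32 ± 0.11 and 0.33 ± 0.12, none past the test over all genes. Within class 1 the same 4 genes were at 0.89, 0.61, 0.52 and 0.35, and within class 2 at −0.20, −0.23, 0.24 and 0.43.

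Limma called 1716 genes, 963 lower and 753 higher, and the split turned to 618 lower and 942 higher after quantile normalization. Once class was a covariate limma called 0, with 1084 at an unadjusted p under 0.05, and edgeR with class called 1. Within class 2 alone the count was 0 (1388 at an unadjusted p under 0.05). Within class 1 alone 4 genes passed, all higher. These were IL2RG, the common gamma chain of interleukin receptors (0.41 ± 0.08), ODF2 (0.47 ± 0.08), MLKL, the executioner of necroptosis (0.51 ± 0.10), and ZNF473; they fall outside the naming rule for this comparison and were picked after their values were seen. Within class 2 IL2RG, ODF2, MLKL and ZNF473 were at −0.06, −0.15, −0.37 and −0.16.

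By the rule, FAM13A (1.04 ± 0.21; ENSG00000138640, chromosome 4, 88725955 to 89111398 of GRCh38, minus strand), CEACAM1 (0.82 ± 0.21), an adhesion receptor, and RGS16 (0.99 ± 0.33) rose. Adding class, FAM13A, CEACAM1 and RGS16 were at 0.77 ± 0.23, 0.57 ± 0.23 and 0.15 ± 0.28, none past the test. They were at 1.34, 1.24 and 0.30 within class 1 and at −0.37, −0.76 and 1.18 within class 2. The other genes named as higher belonged to translation and share reads with near-identical copies, so they are uncertain. They were RPS26 (2.07 ± 0.50), RPL21 (1.77 ± 0.44), RPL39 (0.94 ± 0.27), EEF1A1 (0.88 ± 0.21), RPL23A (0.88 ± 0.20), RPL7 (0.84 ± 0.22) and PABPC3 (0.78 ± 0.21), and with class as a covariate they were at 0.32, 0.07, 0.07, 0.02, 0.09, −0.06 and 0.28. Lower were CCL3 (−2.37 ± 0.54), uncertain here too, CXCL8 (−1.75 ± 0.57), FCAR (−1.58 ± 0.54), the myeloid IgA receptor gene, CFD (−1.55 ± 0.44), the complement factor D gene, and HK3 (−1.41 ± 0.49). C4orf48 (−2.01 ± 0.46), TMEM238 (−1.99 ± 0.55), KCNMA1 (−1.53 ± 0.38), PTCRA (−1.50 ± 0.46) and TXNDC5 (−1.45 ± 0.50) were lower too. Adding class, CCL3, CXCL8, FCAR, CFD and HK3 were at −0.59, −0.20, −0.25, −0.14 and −0.33, C4orf48, TMEM238, KCNMA1 and PTCRA at −0.61, −0.27, −0.53 and −0.54, and TXNDC5 turned to 0.06 ± 0.38. These 10 lay between −1.49 (C4orf48) and −0.39 (CFD) within class 1 and between −1.48 (HK3) and 0.23 (C4orf48) within class 2.

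Of 29 T cell receptor signalling genes 5 rose and 0 fell, among them FYN (0.23 ± 0.05), PRKCQ (0.40 ± 0.10), CD3E (0.27 ± 0.08) and NFATC2 (0.23 ± 0.07), with 5 adjusted over the list alone (camera adjusted p = 0.0054; adjusted p = 0.570 with an estimated correlation; camera adjusted p = 0.794 with class as a covariate). Of 24 glycolysis genes 4 rose, with lactate dehydrogenase A (LDHA) at 0.51 ± 0.11 and the glucose transporter gene SLC2A3 at 0.73 ± 0.23 and 6 adjusted over the list alone (camera adjusted p = 0.0023; adjusted p = 0.570 with an estimated correlation). Of 26 unfolded protein and heat shock genes 3 rose, including HSP90AB1 (0.35 ± 0.09) and HSPD1 (0.44 ± 0.11), and 4 adjusted over the list alone (camera adjusted p = 8.84e-04; adjusted p = 0.570 with an estimated correlation). Of 75 oxidative phosphorylation genes 12 fell and 2 rose, with NDUFC1 at −0.47 ± 0.13, NDUFB7 at −0.71 ± 0.19 and COX5B at −0.45 ± 0.12, and 21 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.0108; adjusted p = 0.755 with an estimated correlation). Of 13 mitochondrially encoded genes 4 rose, such as MT-CYB at 0.43 ± 0.13, and 6 adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.732 with an estimated correlation). Monocyte markers were lower by list, with a median of −0.71 and 0 of 19 past the test (camera adjusted p = 0.0023; adjusted p = 0.732 with an estimated correlation), and 1 of 13 B cell markers, PAX5 (−1.13 ± 0.38), fell (camera adjusted p = 0.0089; adjusted p = 0.732 with an estimated correlation). NDUFC1, NDUFB7 and COX5B were at −0.08, −0.11 and −0.10 with class as a covariate, none past the test, and turned to 0.03, 0.08 and 0.19 within class 2, where NFATC2 turned to −0.12.

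Camera called 10 of 36 lists in this comparison, and 4 kept direction and call with class as a covariate. These were the regulatory T cell and Th2 lists, glycolysis and the mitochondrially encoded genes (camera adjusted p = 0.0125 and 0.0033 for the latter pair; adjusted p = 0.943 for each with an estimated correlation as well). The call was lost for the T cell receptor list, for unfolded protein and heat shock (camera adjusted p = 0.067), oxidative phosphorylation (0.917), monocyte markers (0.534), B cell markers (0.917) and eosinophil and basophil markers (0.413). The monocyte list then had a median of 0.13, against −0.71 without class. After quantile normalization the medians of the T cell receptor list, glycolysis and the mitochondrially encoded genes were 0.02, 0.03 and 0.03, against 0.09, 0.11 and 0.26.

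Asthma among healthy weight children was compared in 20 libraries against 20. The zinc finger gene ZNF473 (ENSG00000142528, chromosome 19, 50025714 to 50053414 of GRCh38, plus strand) rose by 0.61 ± 0.11 on the log2 scale (SE; limma adjusted p = 0.0024), RBM6, an RNA-binding protein gene, by 0.50 ± 0.10, and LCP2, the T cell receptor adaptor SLP-76, by 0.46 ± 0.12. CLIP3 (0.84 ± 0.22) and CEP19 (0.62 ± 0.16) also rose. SOCS1, an inhibitor of cytokine signalling, fell by 0.74 ± 0.19, and the kinase gene PIM3 fell by 0.89 ± 0.22. ZNRF2 (−0.55 ± 0.12), MRPS28 (−0.54 ± 0.14) and ADO (−0.52 ± 0.12) fell as well.

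Limma called 98 genes, 72 higher and 26 lower. The split turned to 119 higher and 572 lower with no filter, 870 and 1235 with arrayWeights, 184 and 232 without the libraries that stood apart, and 951 and 1827 with residual components. Adding class as a covariate, it called 0, with 1656 at an unadjusted p under 0.05, and edgeR with class called 3; ZNF473 and SOCS1 were then at 0.48 ± 0.11 and −0.80 ± 0.20. CLIP3, CEP19, RBM6 and LCP2 were at 0.69, 0.42, 0.39 and 0.33, and PIM3, ZNRF2, MRPS28 and ADO at −0.57, −0.35, −0.38 and −0.33. Over the 98 genes the median absolute log2 difference went from 0.346 to 0.263 (median SE 0.0823 to 0.0792), with a median ratio of 0.704 and the same sign in 98. The median ratio was 1.08 within class 1 and 0.420 within class 2. Within class 1 only ODF2, picked after its value was seen, passed (0.51 ± 0.09), and within class 2 limma called 0 (1582 at an unadjusted p under 0.05). Of 29 T cell receptor genes 2 rose and 4 adjusted over the list alone, including FYN (0.27 ± 0.06; camera adjusted p = 0.0018 for the list; adjusted p = 0.653 with an estimated correlation). The regulatory T cell and Th2 lists were higher with 0 members past the test over all genes and 3 and 1 adjusted over the list alone, FOXP3 at 0.46 ± 0.12 and GATA3 at 0.43 ± 0.12 (camera adjusted p = 0.037 and 0.0355; adjusted p = 0.867 and 0.867 with an estimated correlation). Oxidative phosphorylation, ribosomal protein and monocyte marker lists were lower, with COX7A2 at −0.26 ± 0.07 and RPLP2 at −0.57 ± 0.17 (camera adjusted p = 0.0028, 0.0355 and 0.0222; adjusted p = 0.867 for each with an estimated correlation). RPLP2 turned to 0.07 within class 2, and the monocyte median of −0.61 was −0.26 in both edgeR and DESeq2. Camera called 6 of 36 lists, 4 of which kept direction and call with class as a covariate; the T cell receptor and monocyte lists did not (camera adjusted p = 0.334 and 0.820).

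Obesity among children without asthma (20 libraries against 20) left no gene past the test. Limma called 0, with 997 at an unadjusted p under 0.05, while edgeR called 17 and DESeq2 87. The smallest p-values belonged to HDLBP (0.38 ± 0.08, SE; limma adjusted p = 0.0889), the gene of the RNA-binding protein vigilin, ZNF473 (0.47 ± 0.11), FAM13A (0.97 ± 0.24), OS9 (0.27 ± 0.07) and PAK1 (0.52 ± 0.13) on the higher side. On the lower side they belonged to EXOSC6 (−0.36 ± 0.09), MZT1 (−0.36 ± 0.10), RHOBTB3 (−0.67 ± 0.21), AP4S1 (−0.20 ± 0.06) and RASSF3 (−0.32 ± 0.10). Adding class left these between 0.25 (OS9) and 0.94 (FAM13A) and between −0.61 (RHOBTB3) and −0.19 (AP4S1). With class as a covariate, and within classes 1, 2 and 3 alone, limma called 0 genes each, with 1204, 708, 1146 and 939 at an unadjusted p under 0.05. Cell cycle genes were higher by list in obese children, 31 of 33 positive and 0 past the test, with the proliferation marker MKI67 at 0.67 ± 0.29 and CDC20 at 0.70 ± 0.34 (camera adjusted p = 6.26e-08; adjusted p = 0.5001 with an estimated correlation). Effector memory and cytotoxic genes were positive in 20 of 20, with CX3CR1 at 1.18 ± 0.36 and FCRL6 at 1.05 ± 0.44 (camera adjusted p = 2.36e-06; adjusted p = 0.5001 with an estimated correlation). Monocyte markers were positive in 19 of 19, with a median of 0.56 (camera adjusted p = 7.83e-04; adjusted p = 0.760 with an estimated correlation). That median was 1.29 in DESeq2 and was larger than by limma in edgeR too. The log2 level of CD14 was 14.10 and 12.33 in single obese no asthma libraries of class 3. It was 10.36 or lower in every other library of both groups. How far those libraries set the monocyte values was not tested, so a rise across the group is not shown. Other cell markers were higher by list too, with 0 members past the test over all genes. The medians were 0.69 for plasma cells, 0.27 for CD8 T cells, 0.44 for platelets and 0.27 for B cells (camera adjusted p = 0.0071, 0.015, 0.0382 and 0.0404; adjusted p = 0.5001, 0.5001, 0.844 and 0.781 with an estimated correlation). Camera called 14 of 36 lists, 13 of which kept direction and call with class as a covariate.

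The interaction asked whether the difference that goes with asthma depends on weight. No gene passed: limma called 0, with 2101 at an unadjusted p under 0.05, while edgeR called 77 and DESeq2 142. The smallest p-values were those of LYSMD2 (0.43 ± 0.11, SE), MAIP1 (0.46 ± 0.12), IBA57 (0.65 ± 0.17), RCL1 (0.45 ± 0.12) and CDC42SE2 (0.42 ± 0.11), and of BTN2A2 (−0.61 ± 0.14), IL10RB (−0.41 ± 0.10), FKBP15 (−0.48 ± 0.12), IDH1 (−0.68 ± 0.17) and HDLBP (−0.40 ± 0.10), each with a limma adjusted p of 0.271. Adding class left these between 0.34 (CDC42SE2) and 0.59 (IBA57) and between −0.64 (IDH1) and −0.37 (HDLBP). Class as a covariate left 0 by limma (1668 at an unadjusted p under 0.05), within class 1 alone 0 (659) and within class 2 alone 703, a count that ranged from 0 to 1823 when any 1 library of obese asthma or healthy weight asthma was left out. Camera called 14 lists in the interaction, of which 11 kept direction and call with class as a covariate and 0 held with an estimated correlation.

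No gene passed in the same direction in all 3 comparisons of obese asthma, where limma's calls as independent lists would give 0.0028; edgeR gave 4 and DESeq2 61. The comparisons against the groups without asthma shared 733 genes, against 128.4 for independent lists and a highest number of 0 over 100 random reassignments of the group labels. Their log2 differences correlated across genes at 0.79, against a median of 0.35 in the reassignments and 0.62 when separate parts of 13 obese asthma libraries were used; genes are not independent replicates. The covariance was 0.134 against a median of 0.0155. These reassignments ignored technical class, which is uneven in a like way in both comparisons. With the labels reassigned within the classes, a check chosen after seeing the data, 20 of 100 gave at least 733 shared genes (median 20, highest 2993), and the median correlation was 0.83 and the median covariance 0.114 (highest 0.171). The observed overlap, correlation and covariance were therefore not beyond those given by the class makeup of the groups. Adjusted for class, the correlation was 0.28 and the covariance 0.0134. With the separate parts 0 genes were shared, limma calling 0 in each comparison at that size.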

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

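The lists below were tested for the interaction as planned before the data were examined, and the values with technical class as a covariate were chosen only after the result was seen. Each list stands here because the difference that goes with asthma differed between obese and healthy weight children by camera's test of the interaction. None of the 14 held with an estimated correlation, where the adjusted p ranged from 0.330 to 0.680, and fry called 1 of them, the CD8 T cell markers. No single gene passed in the interaction by limma, with 2101 at an unadjusted p under 0.05; edgeR called 77 and DESeq2 142.

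Effector memory and cytotoxic genes had a median log2 interaction of −0.74 (camera adjusted p = 5.73e-08), with 5 of 20 lower adjusted over the list alone and CX3CR1 at −1.84 ± 0.48, FCRL6 at −2.14 ± 0.58 and GZMH at −1.72 ± 0.67 (SE). Cell cycle genes were at a median of −0.44 (camera adjusted p = 2.44e-05). Type I interferon genes were at −0.31 (camera adjusted p = 4.55e-05), with OAS1 at −1.11 ± 0.41 and IFIT3 at −1.11 ± 0.48. Cytosolic ribosomal proteins were at 0.13 (camera adjusted p = 4.55e-05). Glucocorticoid response genes were at 0.27 (camera adjusted p = 2.76e-04), with 5 of 22 higher adjusted over the list alone and DDIT4 at 0.58 ± 0.19. NF-kB and TNF genes were at 0.17 (camera adjusted p = 3.73e-04), with 2 of 25 higher adjusted over the list alone, BCL3 at 0.72 ± 0.24 and NFKB1 at 0.45 ± 0.15.

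Insulin, PI3K and mTOR genes had a median of 0.14 (camera adjusted p = 0.0047), with IRS2 at 0.70 ± 0.21. Notch and Wnt genes were at 0.16 (camera adjusted p = 0.0127) and immediate early genes at 0.21 (camera adjusted p = 0.0252), though at 0.02 in both edgeR and DESeq2. Markers of other cells were lower as well. Monocyte markers had a median of −0.75 (camera adjusted p = 0.0043), CD8 T cell markers −0.75 (0.0058), B cell markers −0.60 (0.0127), plasma cell markers −1.08 (0.0252), and gamma delta and MAIT cell markers −0.59 (0.0275). The monocyte median was −1.73 in edgeR and −1.79 in DESeq2. With class as a covariate 11 of the 14 lists kept direction and call by camera.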

How the results depend on the processing

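The fits with technical class, within a class and on thinned reads were chosen only after the result was seen, and all others were planned. Over 174 gene values that were followed and 3649 alternatives, 2643 kept direction and side of the threshold, 803 lost the call, 155 gained it and 48 reversed; the cause was not tested. At gene level all 174 kept both with a pseudocount of 5. Fits with class, or within a class, hold fewer libraries per group or spend degrees of freedom, and class is uneven over the groups. Low depth limits the precision of low genes.

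For obese asthma against obese no asthma (2571 genes as fixed), the count was 6602 with limma arrayWeights, 4361 with DESeq2, 0 with cell-mixture covariates (393 at an unadjusted p under 0.05), 1572 with a sex-linked covariate, 7134 with residual components and 1660 without the 3 libraries that stood apart, 1 each of obese asthma, obese no asthma and healthy weight asthma. It was 0 with class, with class and 4 pseudogene components, and with class and cell-mixture covariates, 3 with class in edgeR, 0 in class 1 and 0 in class 2 (limma, 582, 925, 334, 315 and 3484 at an unadjusted p under 0.05 for the counts of 0). Against healthy weight asthma (1 as fixed) it was 4 with arrayWeights, 25 with edgeR, 190 with DESeq2, 872 with residual components, 94 with class in edgeR, 0 in class 1 (455) and 1852 in class 2. Against healthy weight no asthma (1716) it was 6170 with no filter, 931 with a mean of at least 50, 5807 with arrayWeights, 116 with cell-mixture covariates, 5684 with residual components, 0 with class, 0 with class and pseudogene components, 0 with class and cell-mixture covariates (1084, 2120 and 1298), 1 with class in edgeR, 4 in class 1 and 0 in class 2 (1388). The share of calls that were higher was 31.1% with no filter against obese no asthma and 15.3% against healthy weight no asthma, and 64.7% there with a mean of at least 50.

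For asthma in healthy weight children (98) the count was 691 with no filter, 165 with quantile normalization, 2105 with arrayWeights, 316 with DESeq2, 2778 with residual components, 416 without the libraries that stood apart, 61 on thinned reads, 0 with class, 0 with class and pseudogene components, 0 with class and cell-mixture covariates (1656, 3207 and 1779), 3 with class in edgeR, 1 in class 1 and 0 in class 2 (1582). For obesity without asthma (0) it was 1 with arrayWeights, 17 with edgeR, 87 with DESeq2, 1 with cell-mixture covariates, 324 with residual components, 1 with class and cell-mixture covariates and 4 with class in edgeR. For the interaction (0) it was 77 with edgeR, 142 with DESeq2, 1831 with residual components, 5 with class in edgeR and 703 in class 2. Genes shared by all 3 comparisons of obese asthma (0) were 4 with edgeR, 61 with DESeq2 and 516 with residual components. The residual components were taken after the group means were removed, so they left the folds unchanged and lowered only the spread. The p-values behind every count with them therefore do not measure the full spread between libraries, and these counts are likely too high. Of 216 list tests camera called 74, 0 with an estimated correlation, and fry called 11.

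The numbers in the labels share no pairing that the data show. Over 88 pairs with the same number the median correlation of deviations was −0.011, against −0.009 for other pairs, 30 pairs were over 0.1, and 3 of 84 libraries correlated best with their own number. Of the same-number pairs 46.6% shared a technical class, against 39.3% of other pairs. Whether a block on the number follows class in part was not tested. With the number as a replicate block limma called 6212, 1346 and 5334 genes in the 3 comparisons of obese asthma, 111 for asthma in healthy weight children, 0 for obesity without asthma (1135 at an unadjusted p under 0.05) and 463 for the interaction, with 1066 shared genes. Only 84 of the 99 libraries share a number with another group. The rest, most of them obese asthma, do not enter the group contrasts of that fit, so its counts rest on fewer libraries.

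Reversed log2 values against obese no asthma were −0.17 for RPS26 and −0.034 for RPL21 in class 1, 0.015 for G0S2, 0.24 for NKG7, −0.22 for FOXP3 and 0.015 for IER3 in class 2, 0.25 for HBB with cell-mixture covariates, 0.20 for HBB with class added, and 0.062 for NKG7 with class in edgeR. Against healthy weight no asthma in class 2 they were −0.37 for FAM13A, −0.76 for CEACAM1, 0.23 for C4orf48, 0.16 for TMEM238, 0.20 for CXCL8, −0.034 for IKZF4, −0.20 for IL2RA, −0.23 for FOXP3, −0.12 for NFATC2, −0.15 for DOCK8, 0.030 for NDUFC1, 0.079 for NDUFB7, 0.19 for COX5B, −0.058 for IL2RG, −0.15 for ODF2, −0.37 for MLKL and −0.16 for ZNF473. With class and pseudogene components they were −0.015 for EEF1A1, −0.10 for RPL7, 0.21 for TMEM238, 0.0645 for CXCL8, 0.073 for CFD, 0.61 for TXNDC5, −0.0072 for PRKCQ, 0.023 for NDUFC1, 0.10 for NDUFB7, 0.021 for COX5B, 0.077 for PAX5 and −0.029 for SLC2A3. RPL7 was −0.059 with class, −0.0765 with class and cell-mixture covariates, −0.054 with class in edgeR and −0.055 in class 1. TXNDC5 was 0.055, 0.14 and 0.032 in the first 3 of these fits, and RGS16 was −0.0215 with class in edgeR. RPLP2 was 0.070 in class 2 for asthma in healthy weight children, and IKZF4 was −0.0073 in class 3 for obesity without asthma.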

Other observations

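The tests with class as a covariate, on thinned reads and with 1 library left out of class 2 were chosen only after the result was seen. The fit with marker levels as covariates was planned, while its use as a test of the folds below was chosen after the result was seen; the other splits were planned, except that those within the classes followed the definition of the classes.

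Some gene groups not described above went both ways between obese children with and without asthma. Of 23 immediate early genes 4 rose and 2 fell, with NR4A2 at 1.23 ± 0.31, RGS1 at 0.98 ± 0.26 and IER3 at −0.997 ± 0.27 (camera adjusted p = 0.253). IFNG, the signature cytokine of Th1 cells, fell by 1.04 ± 0.27, the single gene of 13 on its list past the test, and FOXP3 rose by 0.36 ± 0.11. Adjusted for class, NR4A2, RGS1, IER3, IFNG and FOXP3 were at 0.44, 0.22, −0.33, −0.79 and 0.32, none past the test, and within class 2 IER3 and FOXP3 turned to 0.0145 and −0.22. Of 41 lipid and cholesterol genes 5 rose and 1 fell (camera adjusted p = 0.113), with 6 and 1 adjusted over the list alone. None of the 10 Th17 genes passed (camera adjusted p = 0.688).

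In splits that ignored the classes, 1 of 100, the real one, gave 2571 genes against obese no asthma (highest other 1709). Likewise 1 of 100 gave 1716 against healthy weight no asthma (highest other 1). For asthma in healthy weight children 1 of 100 gave 98 (highest other 0). These counts went beyond groups drawn without regard to class, but such splits also change each group's class makeup and leave chance within classes open. Nor could chance be excluded for the single gene against healthy weight asthma, where 8 of 100 splits gave as many. The highest other gave 331, which points to a structure of the samples whose cause was not tested. For obesity without asthma, the interaction and the genes shared by all 3 comparisons, where the real count was 0, 100 of 100 splits gave as many by construction (highest other 0), which decides nothing. Within the classes 6 of 100 splits gave 98 genes or more for asthma in healthy weight children, with a highest other of 767, so chance was not excluded there. Nor was it for the 2571 and 1716 genes, with 15 and 12 of 100.

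The 2571 and 1716 genes may reflect the technical classes, as splits made within the classes gave as many genes in 15 and 12 of 100, with a highest other of 6524 and 3527. With class as a covariate the called genes had a median ratio of log2 folds of 0.374 and 0.366, from 0.475 to 0.165 (median SE 0.146 to 0.134) and from 0.544 to 0.195 (0.166 to 0.147), while the ratio was 0.305 and 0.633 within class 1 and 0.611 and 0.0844 within class 2, so the classes are not shown to be the whole cause. Depth alone is argued against, since 1851 and 1099 of these genes were still called on thinned reads. Cells of another type stay open for the genes called lower and higher against obese no asthma, with ratios of 0.320 and 0.324 given marker levels as covariates. The medians went from −0.71 to −0.19 and from 0.32 to 0.11 (SE 0.216 to 0.186 and 0.0984 to 0.0951). All 19 of 19 monocyte markers were lower. Plain dilution of T cell RNA stays undecided for those called higher. The T cell receptor list, called higher by camera with 17 of 29 members positive, had a median of 0.070 ± 0.199 (SD of its members) against 0.32. The genes called higher were chosen for passing the test and the list was not, so its lower median cannot decide on dilution. A biological difference of asthma in obese children stays open as untested in other libraries; here limma called 0 genes with class as a covariate (582 at an unadjusted p under 0.05), which does not show that the groups were alike.

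BCL3 was higher in obese asthma than in healthy weight asthma. The classes alone do not account for the difference seen in these libraries, since the log2 difference was 0.65 in class 1 alone, against 0.88, though it did not pass there. BCL3 was picked for its pooled difference and class 1 holds most of the libraries compared, so the class 1 value is not independent support. With monocyte, platelet, B cell and red blood cell marker levels as covariates the log2 difference was 0.87, which argues against these cells as the whole cause. Cells of other types, among them the gamma delta and MAIT cells whose markers were called lower, were not covariates and stay open. Chance among the libraries stays open, because 12 of 100 splits within the classes called at least 1 gene with class as a covariate, with a highest other of 3058. A difference that goes with obesity among children with asthma may be a further explanation and was not tested in other libraries.

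Within class 2 limma called 1852 genes between obese asthma and healthy weight asthma, with 5 and 6 libraries. Of 100 splits of these libraries 1, the real one, gave as many (highest other 2). The classes were defined after the data were examined, and the same comparison within class 1 called 0 genes. These splits therefore do not exclude chance. A few libraries may set the count, which was 149, 176, 1866, 2401 and 2614 when each obese asthma library was left out, and 613, 692, 835, 1096, 1278 and 1949 when each healthy weight asthma library was. The difference in weight stays open as untested.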
